A study of Ovis aries with 12 samples.

How the data were processed

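Total RNA from longissimus dorsi of 12 lambs, 6 callipyge and 6 normal, was labelled with biotin and hybridised to Affymetrix bovine expression arrays, with 1 array per lamb. Lambs were grouped by genotype and by age (10, 20 or 30 days) from the labels, with 2 in each of 6 groups. The deposited values are intensities per probe set on a linear scale, which the authors made with MAS5 in GCOS. The labels give neither a version nor a scaling target. The table held 24128 probe sets and 0 missing values. The number of arrays limits the precision, and sheep RNA was read by probes made for cattle.

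The trimmed means of the arrays, with 2% left out at each end, ran from 55.7 to 105.7, a ratio of 1.90. The rule set for a ratio above 1.5 was applied, and each array was scaled to the mean of the trimmed means, 79.2. Values were then taken as log2 of the scaled intensity plus 16. The 112 control probe sets were left out, which left 24016. Probe sets whose mean over all arrays lay below the median of 5.25 were left out as dim, which left 12008. Gene symbols came from the array's annotation: 13292 probe sets had 1 symbol, 86 had several and 10638 had none. The 7927 tested probe sets with 1 symbol covered 6346 genes. A probe set with several symbols or none was not named, and probe set identifiers are not printed here.

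Each probe set was fitted with limma 3.58.1 in R 4.3.3 with a mean for each of the 6 groups and variances shared with a trend on brightness (6 residual and 6.93 prior degrees of freedom). Contrasts were the genotype difference averaged over ages and at each age, the interaction of genotype and age, the age effect over all 3 ages and the change from 10 to 30 days, the last pair averaged over genotypes. P values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. For genes at the callipyge locus, and for lists, two-sided exact permutation tests relabelled genotype within age (216 relabelings) or the ages within genotype (8100).

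The genes named were fixed by a rule. For genotype averaged over ages they were the genes of the callipyge locus and, of genes with the same sign at all 3 ages, the 12 that rose and the 12 that fell the most. For each age and for the change with age they were up to 6 that rose and 6 that fell the most. Where no gene passed, they were the 3 with the smallest p in each direction. For each list they were up to 4 members with the smallest p. A gene with several probe sets is represented by the one with the smallest p, and in lists by the brightest. Outside the lists, the other tested probe sets of a gene that the rule named as changed are given in the same paragraph, as are those of the callipyge locus. The samples, the comparisons and tests, the rule for named genes, the lists and most alternatives were set before the data were examined.

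The 32 gene lists covered the callipyge locus, other imprinted genes, published callipyge muscle genes, fibre types, developmental muscle genes, metabolism, protein synthesis and breakdown, signalling, chromatin, stress, and markers of other cell types. camera in limma tested each list of at least 5 measured genes, which 30 were, with a preset correlation of 0.01, and again with an estimated correlation. Each list was also adjusted over the list alone.

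The alternatives were another threshold (0.10), pseudocounts of 1 and 64, no filter or a filter at the 75th percentile, quantile normalization, median centring, least squares without shared variance, robust variances, array weights, other choices of probe set in lists, an estimated correlation, a term for replicate number, and each array left out in turn. After the data were seen, no scaling, leaving out both 30 day arrays that stood apart, and an exact permutation of list means were added.

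The model was tested on simulated data with 100 changed genes of each size. These were drawn only from probe sets that passed the brightness filter in the real data, so the rates do not cover dim ones. The filter was applied again to the simulated values. For genotype averaged over ages it recovered 74% of 2-fold and 83% of 4-fold changes. At single ages it recovered 35% to 45% of 2-fold and 83% to 86% of 4-fold changes, and for the interaction 5% and 56%. For the change from 10 to 30 days it recovered 62% and 84%, and for the age effect 66% and 81%. False calls made up 2.42% to 7.58% of the calls. The simulation gave each probe set independent normal noise in a single run per comparison, so these rates need not hold for the real arrays. For genotype the filter kept 83 of the 100 genes with 4-fold changes, so those not recovered were lost there. Detection calls were not in the table and were not used. Some named-gene results are not reported here.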

Results

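Gene expression was measured in longissimus dorsi, the long loin muscle of the back, of 12 lambs. Callipyge is an inherited overgrowth of muscle that becomes visible in the weeks after birth, and the labels place each lamb as callipyge or normal. The 6 groups joined these genotypes to ages of 10, 20 and 30 days, with 2 lambs in each, so that 6 callipyge lambs stood against 6 normal lambs and 4 lambs stood at each age. Each lamb gave 1 bovine expression array with 24128 probe sets, read with sheep RNA. The trimmed mean signal of the arrays ran from 55.7 to 105.7, and the number of arrays limits the precision of every value.

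Across probe sets, which are not independent of each other, replicate lambs correlated between r = 0.956 and r = 0.969, and the lowest value between any 2 arrays was 0.941. The first component of the log2 values held 17.1% of the variance and the next held 14.4%. The arrays of callipyge 30 day replicate 2 and normal 30 day replicate 2 stood apart from the other lambs of that age, with first component scores of 15.9 and 27.5 against 6.43 and 8.77. Their mean correlations with the other arrays were the lowest, at 0.953 and 0.951. Normal 10 day replicates 1 and 2 lay as far out on the other side, with scores of -22.0 and -17.0, and replicate 1 had the next lowest mean correlation, 0.955. The GAPDH signal at the 3' end exceeded that at the 5' end by 0.29 ± 0.04 on the log2 scale (SD, n = 6) in callipyge and by 0.35 ± 0.10 in normal lambs (two-sided exact permutation p = 0.241). The highest GAPDH value was 0.53, in normal 20 day replicate 1, and the next was 0.37, in normal 30 day replicate 2. The trimmed mean signal before scaling differed by -0.22 on the log2 scale between callipyge and normal lambs (exact permutation p = 0.120) and by 0.30 between 30 and 10 days (exact permutation p = 0.0585).

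The main question of the series is which genes differ in callipyge muscle as hypertrophy sets in. DLK1, a paternally expressed membrane protein of the imprinted cluster that holds the callipyge mutation, rose the most: 5.21-fold in callipyge lambs averaged over the ages (log2 2.38 ± 0.15 SE, 6 lambs against 6, adjusted p = 7.25e-06). Callipyge muscle stood at 10.86 ± 0.32 (SD, n = 6) on the log2 scale and normal muscle at 8.48 ± 0.45. MEG3, a maternally expressed non-coding RNA of the same cluster, rose 4.73-fold (log2 2.24 ± 0.32, adjusted p = 0.00582). For both genes all 6 callipyge lambs lay above both normal lambs of their age, and the two-sided exact permutation p was 0.00926, the smallest that 216 relabelings within age can give. A further DLK1 probe set rose by log2 0.81 ± 0.13 (adjusted p = 0.0141). The other MEG3 probe sets gave 1.19 (adjusted p = 0.020), 0.43 (0.452), 0.15 (0.705) and 0.02 (0.986), so the probe sets of this gene differed in response.

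WARS1, a tRNA synthetase gene at the edge of the cluster, did not pass in any of its 4 tested probe sets. The brightest gave log2 0.25 ± 0.15 (adjusted p = 0.538), another went the other way at -0.45 (adjusted p = 0.353, two-sided exact permutation p = 0.0185), and the rest gave 0.32 (adjusted p = 0.533) and 0.01 (adjusted p = 0.987). WDR25 at 0.09 and MEG8 at 0.07 lay among the dim probe sets outside the tests. RTL1, BEGAIN and DIO3 carried no named probe set in the annotation used here. Of the 3 cluster genes tested, 2 rose over all probe sets and 2 adjusted over the list alone.

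In the named genes outside the cluster, DNTTIP1, a subunit of a histone deacetylase complex, rose by log2 1.73 ± 0.15 (3.33-fold, adjusted p = 0.000119). METTL21E, of a family of lysine methyltransferases, rose by 1.56 ± 0.14 (adjusted p = 0.000233), and a further probe set of this gene gave 1.81. PARK7, a redox-responsive protein, rose by 1.15 ± 0.12 (adjusted p = 0.000552). RPS6KA3, a growth-factor kinase, rose by 0.83 ± 0.11. DOK2 rose by 1.24, UCHL1 by 0.93, STK17A by 0.85 and APOD by 0.82. A further DOK2 probe set gave 0.24 (adjusted p = 0.716), and further APOD probe sets gave 0.54 (adjusted p = 0.291) and -0.11 (adjusted p = 0.854). With no scaling RPS6KA3 stood at 0.61 (adjusted p = 0.119), STK17A at 0.67 (adjusted p = 0.0938) and APOD at 0.59 (adjusted p = 0.149), and none of the 3 passed. The genes named here had adjusted p of up to 0.0362.

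The genes named as lower in callipyge muscle followed from the same rule. IDH2, the mitochondrial isocitrate dehydrogenase, fell by 0.93 ± 0.13 on the log2 scale (adjusted p = 0.00582), and UQCRQ, a subunit of respiratory complex III, fell by 0.99 ± 0.15 (adjusted p = 0.00910). KLF10, a zinc finger transcription factor, fell by 1.17 ± 0.15 (adjusted p = 0.00266), and GPC1, a heparan sulfate proteoglycan of the cell surface, fell by 1.07 ± 0.15. RAMP1, a partner of the calcitonin receptor-like receptor, fell by 1.00 ± 0.17. The other named genes that fell were RGR at -1.23, TTYH1 at -1.21, MADCAM1 at -1.19, PPP4R4 at -1.11, SHFL at -1.09, GALNT17 at -0.94 and AKR1C4 at -0.94. These are means over the ages. TTYH1 stood at -2.14 at 10 days and -0.07 at 30 days, UQCRQ at -1.96 and -0.23, and MADCAM1 at -0.37 and -1.49, though no interaction with age passed. Of the other AKR1C4 probe sets the brightest gave -0.06 (adjusted p = 0.940) and the dimmer ones -0.10 (0.845) and -0.74 (0.130). A further KLF10 probe set gave -0.70 (adjusted p = 0.417), a further RAMP1 probe set -0.74 (adjusted p = 0.0686), and a brighter MADCAM1 probe set gave 0.14 (adjusted p = 0.775). All 6 callipyge lambs lay beyond both normal lambs of their age for 19 of the 24 genes that the naming rule gave, 5 of 6 did for DOK2, TTYH1, RAMP1 and UQCRQ, and 4 of 6 did for UCHL1. The rule picked these genes by their values in the same lambs, so this describes them and adds no evidence. Of probe sets with no gene symbol, the one with the smallest p rose by 1.35 ± 0.11 (adjusted p = 0.000108). Leaving out 1 array ended the calls of 10 of the 24 genes, and each of the 12 arrays ended at least 1. The largest adjusted p for 9 of these was 0.116 for UCHL1 without callipyge 30 day replicate 2, 0.107 for STK17A and 0.0886 for AKR1C4 and 0.0661 for RAMP1 without callipyge 20 day replicate 1, 0.104 for GALNT17 and 0.0923 for DOK2 without callipyge 10 day replicate 1, 0.0950 for MADCAM1 and 0.0890 for SHFL without normal 20 day replicate 2, and 0.0504 for RGR without normal 10 day replicate 1. Without both 30 day arrays that stood apart APOD, PPP4R4 and UQCRQ did not pass, with adjusted p of 0.0552, 0.0635 and 0.0552, nor did DOK2, UCHL1, STK17A, SHFL, RAMP1, GALNT17 and AKR1C4. With a pseudocount of 1 GALNT17 had an adjusted p of 0.0549. Ordinary least squares ended the call of every gene named for genotype except DLK1. The size of change in dim genes depended on the pseudocount. With 1 and 64 in place of 16 it was 1.82 and 0.65 for DOK2, 1.37 and 0.49 for UCHL1, 1.12 and 0.48 for STK17A, -1.98 and -0.61 for RGR, -1.81 and -0.65 for TTYH1, -1.61 and -0.69 for MADCAM1, -1.35 and -0.73 for PPP4R4, -1.72 and -0.53 for SHFL, -1.56 and -0.56 for GPC1, -1.40 and -0.54 for RAMP1, and -1.55 and -0.44 for GALNT17.

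Of 12008 probe sets tested with limma, 106 passed an adjusted p of 0.05 for genotype averaged over ages, of which 68 rose and 38 fell; with no scaling 17 rose and 83 fell. The 106 covered 70 genes by symbol, and 105 of the 106 had the same sign at all 3 ages. Their choice by the mean over the ages favours a shared sign. Over all tested probe sets the genotype difference correlated between ages at r = 0.181 to 0.211. At an unadjusted p under 0.05 there were 1412 probe sets, where 600.4 would follow from chance. Callipyge and normal lambs did not overlap for 124 of all tested probe sets, where chance gives 0.216%. Of these, 57 were among the 106, which were chosen on the same values. The count was 50 and 56 without callipyge 10 day replicates 1 and 2, 43 and 44 without callipyge 20 day replicates 1 and 2, 56 without callipyge 30 day replicate 2, 47 and 49 without normal 10 day replicates 1 and 2, and 52 and 41 without normal 20 day replicates 1 and 2. With ordinary least squares in place of limma's shared variance it was 3, and without both 30 day arrays that stood apart it was 32.

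**Figure D1:**
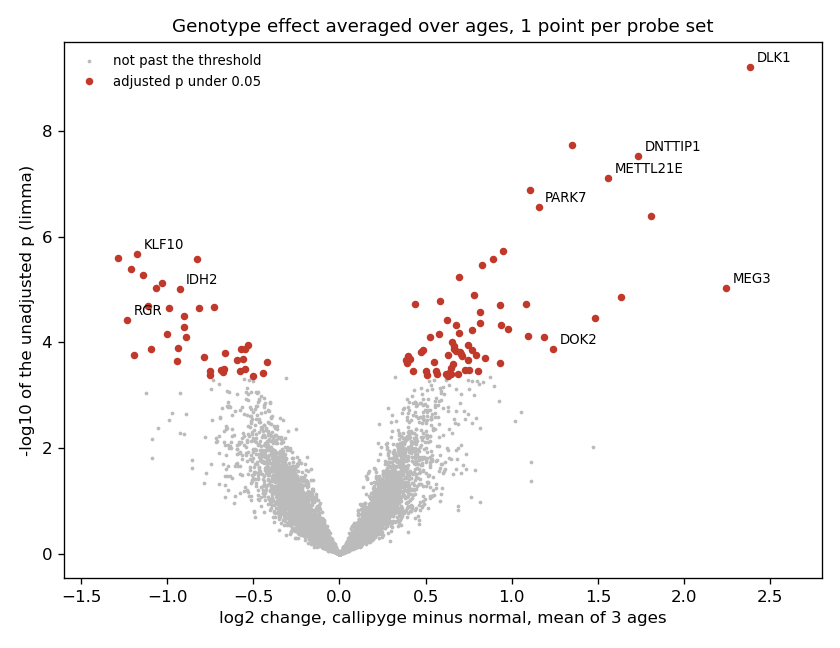
Log2 change of callipyge over normal muscle averaged over 3 ages (x axis) against -log10 of the unadjusted limma p (y axis), with 1 point per tested probe set. Red points are the 106 probe sets with an adjusted p under 0.05; DLK1 at 2.38 lies farthest to the right.

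**Figure D2:**
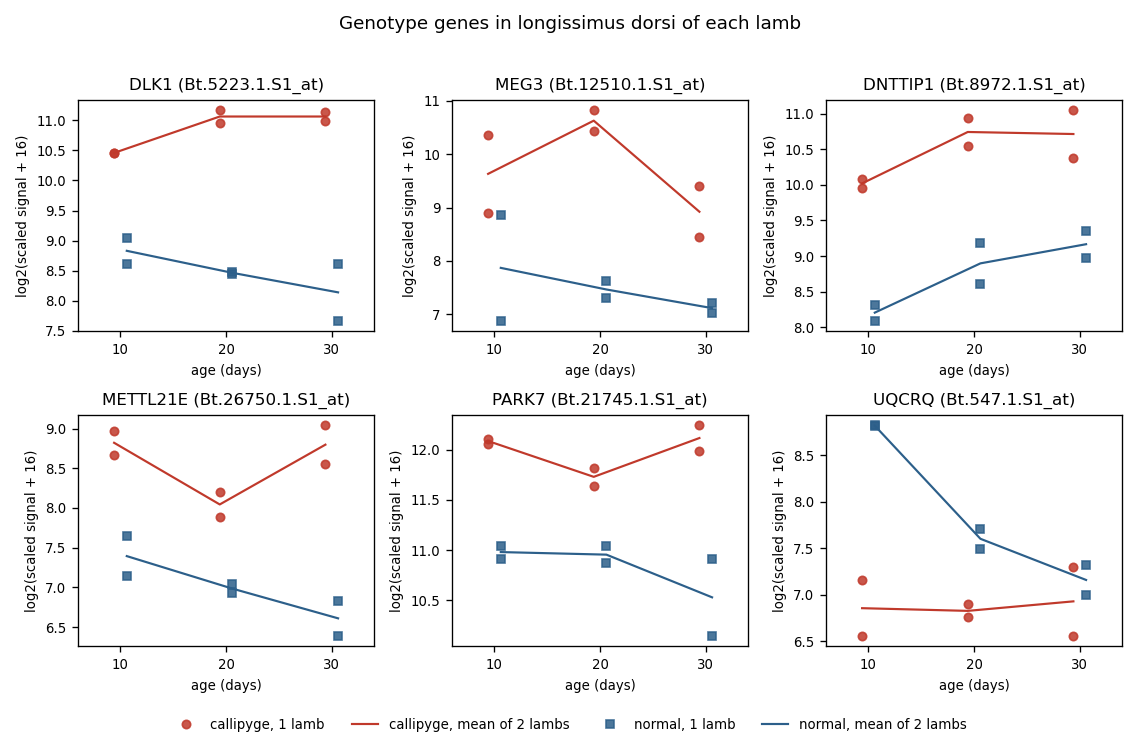
Log2 of the scaled signal plus 16 (y axis) against age in days (x axis) for 6 genes; each point is 1 lamb (circles callipyge, squares normal) and each line joins the means of 2 lambs. DLK1, MEG3, DNTTIP1, METTL21E and PARK7 lie higher in callipyge lambs at each age, and the UQCRQ difference runs from -1.96 at 10 days to -0.23 at 30 days.

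Gene lists fixed in advance were then tested, those of muscle metabolism first. Of 24 measured glycolysis and glycogen genes, 3 rose over all genes and 7 rose adjusted over the list alone, and 19 lay above 0. PFKM, the muscle phosphofructokinase, rose by 0.44 ± 0.07 (adjusted p = 0.00891), PFKFB1 rose by 0.70 ± 0.13 and PGM1, a phosphoglucomutase, by 0.40 ± 0.08. The list passed camera, a test of a list against all other genes (median 0.18, adjusted p = 1.14e-05; adjusted p = 0.176 with an estimated correlation). All 6 callipyge lambs lay above both normal lambs of their age for its mean relative to all genes. With no scaling of the arrays its median was -0.04, while the median of all probe sets was -0.19, so list changes are given relative to all genes.

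Lists of oxidative metabolism lay lower in callipyge muscle relative to all genes, averaged over the ages. The median difference of respiratory chain genes was -0.33, -0.18 and -0.01 at 10, 20 and 30 days, so it was not seen at 30 days. Of 71 respiratory chain (oxidative phosphorylation) genes, 1 fell over all genes, UQCRQ, and 12 fell adjusted over the list alone, and 11 lay above 0 (median -0.16, adjusted p = 1.94e-08; adjusted p = 0.514 with an estimated correlation). With no scaling its median was -0.38, with all probe sets at -0.19. NDUFS7, a complex I subunit, stood at -0.40 and UQCRH at -0.43, both passing over the list alone. Of 18 TCA cycle genes, 1 fell over all genes, IDH2, and 8 over the list alone (median -0.19, adjusted p = 9.61e-05; adjusted p = 0.514 with an estimated correlation). Of 26 fatty acid oxidation genes, 0 passed over all genes, while 6 fell and 2 rose over the list alone, among them ACADM at -1.12 and UCP3 at 0.56 (median -0.20, adjusted p = 0.0316; adjusted p = 0.395 with an estimated correlation). Without both 30 day arrays that stood apart the fatty acid list gave an adjusted p of 0.0542, and with all probe sets of each gene 0.0970 (median -0.13). That list's adjusted p was 0.113 without callipyge 10 day replicate 1, 0.0643 without callipyge 20 day replicate 1 and 0.119 without normal 20 day replicate 1, where its median was -0.07. For the respiratory, TCA cycle and fatty acid lists, 5 of 6 callipyge lambs lay below both normal lambs of their age.

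Slow fibre genes lay at or below the normal level in callipyge muscle. Of 16 measured, 0 lay above 0, and LDHB, the heart form of lactate dehydrogenase, fell by 0.89 ± 0.16 (adjusted p = 0.0201). MB, myoglobin, passed over the list alone at -0.61, where 2 fell in all. The list passed camera (median -0.21, adjusted p = 0.000732; adjusted p = 0.514 with an estimated correlation), and without both 30 day arrays that stood apart its median was -0.08 (adjusted p = 0.0628). With 1 array left out the slow fibre median nearest 0 was -0.13, without normal 30 day replicate 2 (adjusted p = 0.0119). The slow myosin gene MYH7 stood at -0.16 ± 0.14 (adjusted p = 0.719). Of 13 fast fibre genes, 0 passed over all genes and 2 rose over the list alone, MYLK2 at 0.79 and ACTN3 at 0.30, and the list did not pass (median 0.05, adjusted p = 0.323). Of 3 erythroid genes, too few for camera, 2 fell over the list alone, CA2 at -0.54 and HBB at -0.61 (median -0.54, two-sided exact permutation p = 0.0370). The other markers of cell types besides muscle did not pass as lists for genotype: endothelial and smooth muscle had a median of -0.12 (adjusted p = 0.117), collagens and matrix -0.09 (0.117), immune cells 0.03 (0.821), adipocytes 0.01 (0.992) and nerve and Schwann cells -0.11 (0.917).

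The proteasome list and that of endoplasmic reticulum stress and heat shock lay higher relative to all genes. Of 28 proteasome genes, 25 lay above 0 and 0 passed alone or over the list (median 0.14, adjusted p = 8.61e-05; adjusted p = 0.514 with an estimated correlation; median -0.07 with no scaling). Of 28 genes of endoplasmic reticulum stress and heat shock, 22 lay above 0, 0 passed over all genes and 5 over the list alone, with BAG3 at 0.49, HSPA8 at 0.34 and HSP90AA1 at 0.40 (median 0.12, adjusted p = 0.000465; adjusted p = 0.514 with an estimated correlation; median -0.08 with no scaling). With 1 array left out the proteasome median ran from 0.10 to 0.20 and the endoplasmic reticulum stress and heat shock one from 0.09 to 0.19, and both passed each time with the preset correlation. Of 60 ribosomal protein genes 14 lay above 0 and 0 passed (median -0.09, adjusted p = 0.0268; adjusted p = 0.719 with an estimated correlation), and this call ended without any of 5 arrays, with an adjusted p of 0.358 without callipyge 30 day replicate 2 (median -0.04), 0.148 without normal 10 day replicate 1, 0.0822 without callipyge 20 day replicate 1, 0.0741 without normal 20 day replicate 2 and 0.0593 without callipyge 10 day replicate 2. For the ribosomal proteins list it was 0.127 with quantile normalization (median -0.06) and 0.311 without both 30 day arrays that stood apart (median -0.03). The list of published callipyge muscle genes rose in 5 of 6 measured members over all genes and in 6 over the list alone (median 1.44, adjusted p = 1.93e-15; adjusted p = 0.0232 with an estimated correlation; median 0.81 with all probe sets of each gene). The list was drawn partly from work on such lambs and is not independent evidence of its direction.

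The remaining lists did not pass for genotype. Of 9 embryonic and neonatal muscle genes 2 rose and 1 fell over the list alone (median 0.19, adjusted p = 0.121). Of 18 other imprinted genes 2 rose over the list alone, NNAT at 0.59 and IGF2 at 0.78 (median -0.09, adjusted p = 0.917). Of 19 calcium handling genes 1 rose over all genes, CAMK2D at 0.69, a calcium-dependent kinase (median 0.04, adjusted p = 0.220). Medians were 0.16 for myogenic regulation (adjusted p = 0.661, MEF2A at 0.40 over the list alone), 0.05 for translation factors (0.0909), 0.04 for ubiquitin ligases and autophagy (0.306), 0.02 for growth signalling (0.917), 0.02 for cAMP signalling (0.588) and -0.02 for the cell cycle (0.954). They were 0.02 for antigen presentation (0.917), -0.07 for interferon response (0.917), -0.07 for immediate early genes (0.428) and -0.11 for circadian and glucocorticoid genes (0.30). The chromatin regulators had a median of 0.02 with a test direction of down (0.917), the adipocyte list had a median of 0.01 with a test direction of down, and the myofibril list had a median of 0.01 and a mean of -0.05 (0.941).

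In all, 9 of 30 lists passed camera for genotype with the preset correlation of 0.01, and 1 with an estimated correlation, that of published genes. In an exact permutation of genotype within age on the list means, chosen after the data were seen, 9 lists had an unadjusted p under 0.05 and 0 passed after adjustment, with 0.119 the adjusted p of glycolysis. Of 100 splits of the lambs, the real one included, 11 gave as many lists.

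**Figure D3:**
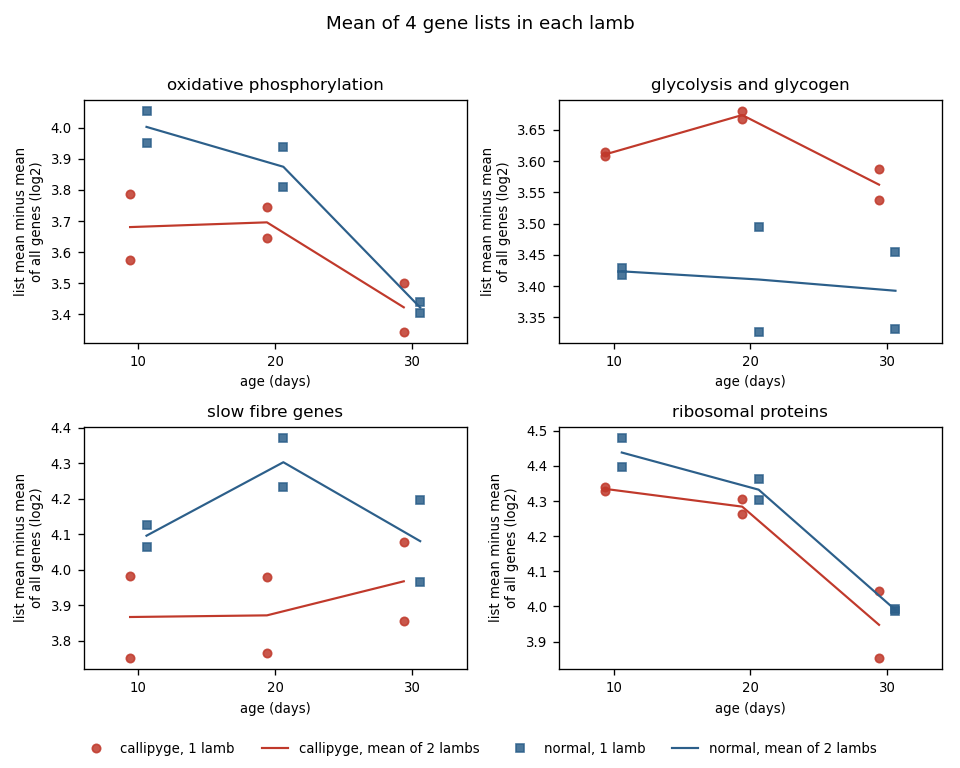
Mean log2 value of 4 gene lists minus the mean of all genes (y axis) against age in days (x axis); each point is 1 lamb (circles callipyge, squares normal) and each line joins the means of 2 lambs. Respiratory chain and ribosomal protein genes lie lower at 30 than at 10 days in all 4 lambs of that age, and glycolysis genes lie higher in callipyge lambs relative to all genes (list median 0.18, and -0.04 with no scaling).

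Each age was then compared alone, to ask when differences begin, with 2 lambs against 2. At 10 days 8 probe sets passed, 5 up and 3 down; with no scaling 0 rose and 5 fell. DNTTIP1 rose by log2 1.81 ± 0.26 (adjusted p = 0.0261), DLK1 by 1.63 ± 0.26 (adjusted p = 0.0485) and SLC16A3, a lactate transporter, by 1.45 ± 0.20 (adjusted p = 0.0252), while TTYH1 fell by 2.14 ± 0.28 and UQCRQ fell by 1.96 ± 0.27 (adjusted p = 0.0252 for both). The TTYH1 change at 10 days was -3.41 with a pseudocount of 1 and -1.08 with 64. Further SLC16A3 probe sets stood at 0.64 (adjusted p = 0.394) and 0.62 (adjusted p = 0.358). With no scaling DNTTIP1 (adjusted p = 0.0620), DLK1 (0.201) and SLC16A3 (0.20) did not pass at 10 days, and DLK1 had 0.0518 with quantile normalization. At 20 days 4 probe sets passed, all up (2 up and 7 down with no scaling), with DLK1 at 2.60 ± 0.26 (adjusted p = 0.00189) and DNTTIP1 at 1.84 ± 0.26 (adjusted p = 0.0219; 0.0615 with no scaling). At 30 days 6 passed, all up (4 up and 0 down with no scaling), with DLK1 at 2.92 ± 0.26 (adjusted p = 0.000476), METTL21E at 2.19 ± 0.25 (adjusted p = 0.00519) and PARK7 at 1.59 ± 0.21 (adjusted p = 0.0110; 0.0781 with no scaling). DLK1 and a probe set with no gene symbol passed at all 3 ages, the latter with 1.20, 1.43 and 1.42 at 10, 20 and 30 days. A further DLK1 probe set gave 0.58 (adjusted p = 0.499), 1.00 and 0.86 (adjusted p = 0.367) at those ages and did not pass. The other probe sets with no symbol that passed stood at 1.24 and -1.21 at 10 days, 1.36 at 20 days and 1.38 at 30 days, and a further METTL21E probe set at 2.77 at 30 days. These were chosen after their values were seen.

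At an unadjusted p under 0.05 there were 1059, 738 and 913 probe sets at 10, 20 and 30 days. Leaving out any of the 10 day arrays, which leaves 1 lamb in that group, gave 0 at 10 days. The DLK1 adjusted p at 10 days was then at most 0.250, without normal 10 day replicate 2, and 0.0788 and 0.0778 without callipyge 20 day replicates 1 and 2, 0.0673 and 0.0661 without normal 20 day replicates 1 and 2, and 0.0607 without either callipyge 30 day array. The 10 day count was 4 without callipyge 20 day replicate 1, 4 without callipyge 20 day replicate 2, and 5 without either normal 20 day array. The 20 day count was 1 without callipyge 10 day replicate 1, 1 without callipyge 10 day replicate 2, 1 without callipyge 20 day replicate 1, 2 without callipyge 20 day replicate 2 and 2 without normal 20 day replicate 1. DNTTIP1 at 20 days then had an adjusted p of 0.0526, 0.0527, 0.101, 0.192 and 0.246, in the order of those arrays. The 30 day count was 1 without callipyge 30 day replicate 2, where METTL21E had an adjusted p of 0.109 and PARK7 of 0.222, and 13 without callipyge 30 day replicate 1. Ordinary least squares gave 0 at each age.

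Whether the genotype difference itself changed with age was asked by the interaction. No probe set passed in limma (0 of 12008, smallest adjusted p = 0.952), with 570 at an unadjusted p under 0.05 where 600.4 would follow from chance. Ordinary least squares also gave 0, and 2 passed without callipyge 20 day replicate 2. The genes with the smallest p, none of which passed, were OLFM1, TTYH1, MEF2C, GIGYF1, NECAP2 and ZBTB16. For TTYH1 the genotype difference changed by log2 2.06 ± 0.39 from 10 to 30 days, for MEF2C, a muscle transcription factor, by 1.36 ± 0.26, and for ZBTB16, a zinc finger factor, by -1.69 ± 0.35 (adjusted p = 0.598 for this change in each, and 0.952 for the interaction over all 3 ages). OLFM1 gave 0.49 ± 0.50, NECAP2 gave -0.35 ± 0.33 and GIGYF1 gave -1.49 ± 0.31. These changes leave out 20 days, which the interaction also covers. With 1 array left out NECAP2 ran from -0.53 to -0.18, and OLFM1 from 0.13 to 0.84 in the 9 fits that kept it. For DLK1 the change from 10 to 30 days was 1.29 ± 0.36 (adjusted p = 0.740 for this change, and 0.992 over all 3 ages), and 0.82 ± 0.28 without normal 30 day replicate 2.

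The time course also shows how loin muscle changed over the first month, averaged over the genotypes. From 10 to 30 days, KLF11, a zinc finger transcription factor, rose 3.90-fold (log2 1.96 ± 0.38, 4 lambs against 4, adjusted p = 0.0243), and LRRC2, a leucine-rich repeat protein, rose 2.83-fold (adjusted p = 0.0304). BNIP3, a receptor for the removal of mitochondria, rose by 1.19 ± 0.23, GPX3, a secreted glutathione peroxidase, by 1.20 ± 0.18, CLIC2 by 1.23 ± 0.22 and BOLA-DQB1, a class II antigen-presenting chain, by 1.24 ± 0.28 (adjusted p = 0.0445). NMRK2, a nicotinamide riboside kinase of muscle, fell by 1.41 ± 0.15 (adjusted p = 0.00381). S100A2, a calcium-binding protein, fell by 1.26 ± 0.20, SOD3, the extracellular superoxide dismutase, fell by 1.24 ± 0.26, PAK1, a kinase, fell by 1.18 ± 0.18, GPT, an alanine aminotransferase, fell by 1.14 ± 0.20 and MADCAM1 fell by 1.22 ± 0.28 (adjusted p = 0.0467). Other probe sets of these genes were weaker or did not pass. KLF11 had 0.48 (adjusted p = 0.378) and 0.76 (0.0651), LRRC2 0.84 (0.123), CLIC2 0.63 (0.242), BNIP3 0.92 (0.0357), PAK1 -0.32 (0.457) and -0.39 (0.549), and a brighter MADCAM1 probe set -0.10 (0.846). With no scaling S100A2 (adjusted p = 0.0610), MADCAM1 (0.0730) and GPT (0.0854) did not pass. BOLA-DQB1 did not pass with a pseudocount of 64 (0.0556), quantile normalization (0.0534), array weights (0.0617) or a replicate block (0.0515). MADCAM1 did not pass with a pseudocount of 64 (0.0724) or quantile normalization (0.0548). All 4 older lambs lay beyond both 10 day lambs of their genotype for 11 of these 12 genes, and 3 of 4 did for MADCAM1. As the genes were picked by their values in the same lambs, this adds no evidence. Without both 30 day arrays that stood apart only NMRK2 of the 12 passed, with LRRC2 at 0.95 and BNIP3 at 0.76. With ordinary least squares 0 of the 12 passed, NMRK2 having an adjusted p of 0.0527 and GPX3 of 0.0847, so that none passed in every setting. With a pseudocount of 1 and of 64 SOD3 stood at -2.22 and -0.57, MADCAM1 at -1.71 and -0.68 and LRRC2 at 1.83 and 0.99. Only NMRK2 and GPX3 passed without each of the 12 arrays in turn, and 11 arrays ended at least 1 of the other calls. The largest adjusted p was 0.104 for KLF11, 0.104 for BNIP3, 0.116 for LRRC2, 0.151 for BOLA-DQB1, 0.0852 for CLIC2, 0.0630 for S100A2, 0.0716 for GPT and 0.0541 for PAK1 without normal 10 day replicate 1, 0.143 for MADCAM1 without callipyge 10 day replicate 1 and 0.105 for SOD3 without callipyge 10 day replicate 2.

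Genes of the respiratory chain and of the ribosome lay lower with age relative to all genes. With no scaling their medians were -0.13 and -0.09, with all probe sets at 0.24, and with quantile normalization the ribosomal proteins list stood at -0.23. Of 71 respiratory chain genes 25 fell over all genes and 55 adjusted over the list alone, and 0 lay above 0, with ATP5MF at -0.81 ± 0.10, ATP5PD at -0.77 ± 0.10 and UQCRH at -0.98 ± 0.13. Its median was -0.43 (camera adjusted p = 2.38e-25; adjusted p = 0.180 with an estimated correlation; exact permutation adjusted p = 0.0241). Of 60 ribosomal protein genes 24 fell over all genes and 55 over the list alone, and 0 lay above 0, with RPL32 at -1.14 ± 0.16, RPS26 at -0.88 ± 0.12 and RPS7 at -0.70 ± 0.10. Its median was -0.39 (camera adjusted p = 2.38e-25; adjusted p = 0.153 with an estimated correlation; exact permutation adjusted p = 0.00741). For both lists all 4 lambs of 30 days lay below both 10 day lambs of their genotype. Of 18 TCA cycle genes 0 fell over all genes and 5 over the list alone (median -0.23, adjusted p = 0.00714; adjusted p = 0.619 with an estimated correlation). The TCA median was 0.07 with no scaling, where the median of all probe sets was 0.24, and its adjusted p was 0.0778 then, 0.195 with quantile normalization (median -0.13), 0.0897 without callipyge 30 day replicate 2 (median -0.16) and 0.0666 without both 30 day arrays that stood apart.

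Further lists lay higher at 30 days relative to all genes by the preset correlation. Of 27 ubiquitin ligase and autophagy genes 1 rose over all genes, BNIP3, and 2 over the list alone, BNIP3 and CAST (median 0.23, adjusted p = 0.000952; adjusted p = 0.180 with an estimated correlation; exact permutation adjusted p = 0.0198). Of 12 circadian and glucocorticoid genes 11 lay above 0 and 0 passed, with ANGPTL4 at 1.14 and CEBPD at 0.95 (median 0.23, adjusted p = 0.00714; adjusted p = 0.153 with an estimated correlation; exact permutation adjusted p = 0.0198). With 1 array left out the circadian and glucocorticoid median ran from 0.20 to 0.35. Of 22 immediate early and stress genes 18 lay above 0, 0 passed over all genes and 1 over the list alone, CCN2 at 0.80 (median 0.33, adjusted p = 0.000249; adjusted p = 0.153 with an estimated correlation). Of 12 interferon response genes 11 lay above 0, 0 passed over all genes and 4 over the list alone, with RSAD2 at 0.68 and IFI27 at 1.11 (median 0.40, adjusted p = 0.000260; adjusted p = 0.367 with an estimated correlation). Without both 30 day arrays that stood apart the interferon response median was 0.19 and that of ubiquitin ligases and autophagy 0.15, and both still passed.

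Lists of immune and vessel genes lay higher with age as well by the preset correlation. The endothelial and smooth muscle rise lay mainly in normal lambs, with list means relative to all genes of 0.33 and 0.77 at 10 and 30 days. In callipyge lambs these means were 0.38 and 0.40. The antigen presentation list had a median of 0.32 (12 genes, 1 over the list alone, BOLA-DRB3 at 1.03; adjusted p = 0.00783; adjusted p = 0.619 with an estimated correlation). The immune cell list had a median of 0.21 (11 genes, 0 alone; adjusted p = 0.0223; adjusted p = 0.635 with an estimated correlation), and the endothelial and smooth muscle list 0.16 (16 genes, 2 over the list alone, TAGLN at 0.57 and TEK at 0.67; adjusted p = 0.0245; adjusted p = 0.569 with an estimated correlation). Without callipyge 30 day replicate 2 the antigen presentation median was 0.16 (adjusted p = 0.151) and the immune cell one 0.17 (0.0618), and without both 30 day arrays that stood apart they were 0.12 (0.251) and 0.18 (0.0666), with endothelial and smooth muscle at 0.33 (0.00130). The immune cell list had a median of 0.11 with a pseudocount of 64 (0.0533) and 0.11 with no filter (0.0928), and an adjusted p of 0.0604 with no scaling. Without callipyge 10 day replicate 1 antigen presentation stood at 0.19 (0.122) and endothelial and smooth muscle at 0.13 (0.0675). Without normal 10 day replicate 1 the immune cell list stood at 0.12 (0.182) and the endothelial and smooth muscle list at 0.04 (0.146). The latter stood at 0.10 without callipyge 30 day replicate 1 (0.246) and at 0.10 without normal 30 day replicate 1 (0.140). With 1 array left out the highest medians were 0.42 for antigen presentation, 0.33 for immune cells and 0.27 for endothelial and smooth muscle. The myofibril list did not pass (24 genes, median -0.01, adjusted p = 0.920).

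The remaining lists did not pass for age. Of 24 chromatin regulators 2 rose over all genes, SMYD2 at 0.61 and EZH1 at 0.80, and 4 over the list alone (median 0.05, adjusted p = 0.215). Of 26 fatty acid oxidation genes UCP3 rose by 0.80 and HADH fell by 0.58 (median 0.15, adjusted p = 0.215). Of 9 embryonic and neonatal muscle genes 2 fell over the list alone, MYH8, the neonatal myosin, at -1.07 and IGF2 at -0.73 (median -0.32, adjusted p = 0.129). Of 18 other imprinted genes 3 fell over the list alone, MEST at -0.74, GNAS at -0.30 and IGF2 (median -0.05, adjusted p = 0.586). Single members passed over all genes in matrix genes (THBS4 at 1.15, list median -0.03, adjusted p = 0.312), glycolysis (GPI at -0.38, -0.08, 0.336), calcium handling (CACNB1 at -0.59, -0.09, 0.670), translation factors (EEF1G at -0.43, -0.09, 0.143), slow fibre genes (SMPX at -0.46, -0.00, 0.803) and published callipyge genes (DNTTIP1 at 0.83, 0.09, 0.199). Medians were -0.14 for fast fibre genes (0.498), -0.26 for the cell cycle (0.226), -0.11 for the proteasome (0.336), 0.09 for endoplasmic reticulum stress and heat shock (0.336), 0.06 for cAMP signalling (0.568), -0.02 for growth signalling (0.923), 0.03 for myogenic regulation (0.857), -0.10 for adipocytes (0.568) and -0.08 for nerve and Schwann cells (0.858). The 3 erythroid genes had a median of 0.15 and the 3 genes of the callipyge cluster -0.04.

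From 10 to 30 days 220 probe sets passed, of which 69 rose and 151 fell, covering 173 genes; with no scaling 223 rose and 5 fell. There were 1965 at an unadjusted p under 0.05. Over all 3 ages together 102 passed, of which 25 rose and 77 fell from 10 to 30 days; with no scaling 80 rose and 4 fell. A total of 7 probe sets passed for both genotype and the change from 10 to 30 days, among them DNTTIP1, KLF10, PAK1, CIAPIN1, MADCAM1 and SLC25A11, names chosen after their values were seen. The count of 220 became 41 and 22 without callipyge 10 day replicates 1 and 2, 18 and 84 without normal 10 day replicates 1 and 2, 63 without callipyge 30 day replicate 2, 89 without normal 30 day replicate 2, and 1 without both of these 30 day arrays. The count of 102 became 0 without callipyge 10 day replicate 1, 2 without callipyge 10 day replicate 2, 12 without either callipyge 20 day array, 0 without callipyge 30 day replicate 2, 6 and 0 without normal 10 day replicates 1 and 2, 13 and 22 without normal 20 day replicates 1 and 2 and 11 without normal 30 day replicate 2. In all, 10 of 30 lists passed camera for this change, 0 with an estimated correlation and 4 by exact permutation, a test chosen after the data were seen, and of 100 splits of the lambs, the real one included, 7 gave as many lists.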

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

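The tests of a haplotype difference, of the muscle fibre share and of a shift between fibre types were chosen after the results were seen, as were no scaling and the removal of both 30 day arrays that stood apart; the other tests were chosen earlier.

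The genotype difference of DLK1 changed by log2 1.29 from 10 to 30 days (SE 0.36, adjusted p = 0.740), which does not pass over all genes. A fixed sequence difference between the haplotypes under the bovine probes would give the same difference at each age; the change was 0.82 without normal 30 day replicate 2 and 1.76 without normal 30 day replicate 1, but the further DLK1 probe set changed by 0.28 ± 0.33, within 1 standard error of 0. In that further probe set the change was -0.08 without normal 30 day replicate 2 and 0.63 without normal 30 day replicate 1, so it was not steady. The widening thus rests on 1 probe set. Averaged over ages the further probe set was also higher in callipyge lambs, by log2 0.81 ± 0.13 (limma adjusted p = 0.0141). A sequence difference stays open for the higher level, but it would have to affect both probe sets. Other scalings gave a DLK1 genotype difference of at least 2.16 (adjusted p = 6.27e-07) and leaving out 1 array at least 2.22 (largest adjusted p = 0.000109), which argues against scaling and against a single lamb. The callipyge genotype stays open beside it.

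Ribosomal protein and respiratory chain genes were lower at 30 than at 10 days, with medians of -0.39 and -0.43. Random lists of like brightness fell too, with medians of -0.15 and -0.13 over 10000 draws (95% within -0.24 to -0.04 and -0.22 to -0.04). The draws for each list could take genes of the other, so their fall does not show that bright probe sets shifted as a class. Both lists, at percentile 0 of the draws, fell further than the draws. The draws took genes as unrelated to each other. With 1 array left out the medians nearest 0 were -0.37 and -0.38, which argues against a single lamb. With an estimated correlation neither list passed camera (adjusted p = 0.153 and 0.180). A lower share of muscle fibres would lower myofibril genes alike, but the myofibril median exceeded the respiratory one by 0.42 (bootstrap 95% limits over genes 0.31 to 0.52). These limits hold the spread between genes and not that between lambs. The myofibril mean relative to all genes was 2.98 and 3.01 at 10 and 30 days in callipyge lambs. In normal lambs it was 3.01 and 3.08, so it did not fall in either genotype. Of other cell types, immune cells (median 0.21) and endothelial and smooth muscle (median 0.16) passed with the preset correlation and not with an estimated one (adjusted p = 0.635 and 0.569). Adipocytes (-0.10) and nerve (-0.08) did not pass. Without normal 10 day replicate 1 the immune and endothelial medians fell to 0.12 (adjusted p = 0.182) and 0.04 (adjusted p = 0.146) and did not pass, so a rise of these types was not steady to the removal of 1 lamb and stays open. Transcript length could not be tested with these values, and postnatal age may account for the fall, with 0 of the 10 age lists passing with an estimated correlation.

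Averaged over ages, respiratory chain genes were lower (median -0.16, and -0.01 at 30 days alone) and glycolysis genes higher (median 0.18) in callipyge lambs relative to all genes. With no scaling the glycolysis median was -0.04. Among random lists of like brightness the scaled medians over the ages lay at percentile 0 (95% within -0.07 to 0.04) and percentile 100 (95% within -0.12 to 0.04). With 1 array left out the medians nearest 0 were -0.12 (adjusted p = 3.33e-05) and 0.16 (adjusted p = 0.000295), which argues against a single lamb. Those values hold the preset correlation of camera, and with an estimated correlation neither list passed (adjusted p = 0.514 and 0.176). A shift from slow to fast fibres cannot be told apart from a metabolic change within fibres, since the slow list lay lower (median -0.21) while the fast list did not pass (median 0.05, adjusted p = 0.323). The slow list itself had an adjusted p of 0.514 with an estimated correlation, and its median was -0.13 without normal 30 day replicate 2 and -0.08 without both 30 day arrays that stood apart (adjusted p = 0.0628). Genotype stays open as an explanation, and may act through either.

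Some lists showed a genotype difference that changed with age by the preset correlation of camera, none of them with an estimated one. For respiratory chain genes the difference changed by 0.15 from 10 to 20 days (adjusted p = 0.0146; adjusted p = 0.902 with an estimated correlation) and by 0.32 from 10 to 30 days (adjusted p = 3.17e-09; adjusted p = 0.904 with an estimated correlation), with medians of -0.33, -0.18 and -0.01 at 10, 20 and 30 days. For immediate early and stress genes it changed by -0.31 from 10 to 20 days (adjusted p = 0.00430; adjusted p = 0.308 with an estimated correlation). For endothelial and smooth muscle genes it changed by -0.38 from 10 to 30 days (adjusted p = 0.0130; adjusted p = 0.904 with an estimated correlation).

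Of 12008 dim probe sets outside the tests, 2 passed for genotype and 8 for the change from 10 to 30 days when no filter was used. These included CCR4 at 0.83 (adjusted p = 0.0299) for genotype, and a dim MYH1 probe set at -1.69, SAA4 at -1.18, AHSG at 1.02, ACKR1 at 0.87 and EDC3 at 0.77 for age, names chosen after their values were seen.

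Other splits of the lambs were counted for each result over all genes. For genotype averaged over ages 1 of 100 splits, the real one, gave as many as 106 probe sets, and the highest other gave 4. For the age effect 1 of 100 gave as many as 102 (highest other 2), and for the change from 10 to 30 days 1 of 100 gave as many as 220 (highest other 3). That is the smallest share 100 splits can give, so it argues against chance for these counts without excluding it. Any real difference enters the spread in the other splits, which lowers their counts. For lists, 11 of 100 splits gave as many as 9 for genotype (highest other 15) and 7 of 100 as many as 10 for age (highest other 12), so chance cannot be excluded for the number of lists.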

How the results depend on the processing

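The settings with no scaling, without both 30 day arrays that stood apart and with exact permutation of list means were chosen after the data were seen. DLK1 for genotype passed in all 22 settings (2.16 to 2.54, largest adjusted p = 0.0437), and the test direction of no called gene or list reversed. With no scaling 4 list medians changed sign: glycolysis to -0.04, proteasome to -0.07 and endoplasmic reticulum stress and heat shock to -0.08 for genotype, and the TCA cycle to 0.07 for age. The counts moved as follows, and where not said otherwise the cause was not tested. At an adjusted p under 0.10, a looser threshold, 192 probe sets passed for the genotype effect averaged over ages (genotype), 27 at 10 days, 10 at 30 days, 248 for the age effect averaged over genotypes (age) and 449 for the age change from 10 to 30 days averaged over genotypes. With no filter, which tests more probe sets, these were 47 for genotype, 0 at 10 days, 2 at 20 days, 20 for age and 87 from 10 to 30 days; a filter at the 75th percentile of brightness gave 159 for age. Pseudocount 1 gave 10 at 30 days. Quantile normalization gave 4 at 10 days (2 up, 2 down) and 26 for age (12 up, 14 down), and from 10 to 30 days 70 up and 96 down. Least squares without shared variance gave 3 for genotype, 0 at 10 days, 0 at 20 days, 0 at 30 days, 2 for age and 15 from 10 to 30 days. Array weights gave 20 at 10 days. No scaling gave 5 at 10 days (0 up, 5 down) and 9 at 20 days (2 up, 7 down); it moved the median of all probe sets by -0.19 for genotype and 0.24 for age, and the calls split into 17 up and 83 down for genotype, 80 and 4 for age, and 223 and 5 from 10 to 30 days, against 68 and 38, 25 and 77, and 69 and 151. Without both 30 day arrays that stood apart, with fewer arrays, counts were 32 for genotype, 16 at 10 days, 1 at 30 days, 1 for the interaction, 1 for age and 1 from 10 to 30 days. With 1 array left out, where a lone lamb is assumed to vary like the other groups, counts ran from 41 to 116 for genotype, 0 to 8 at 10 days, 1 to 5 at 20 days, 1 to 13 at 30 days, 0 to 2 for the interaction, 0 to 118 for age and 18 to 279 from 10 to 30 days. For lists, 1 passed for genotype and 0 for age with an estimated correlation, and 0 and 4 by exact permutation. The exact permutation counts cannot be compared, since the smallest exact p was 0.00926 for genotype and 0.000247 for age. Residual correlations gave little sign that replicate numbers paired the lambs (-0.06 to 0.11, 1 of 15 over 0.1). The highest, 0.11, was between the callipyge and normal 30 day groups, whose replicate 2 arrays stood apart. A replicate block gave 96 for genotype, 10 at 10 days, 5 at 20 days and 9 at 30 days. It gave 0 for the interaction, 116 for age and 235 from 10 to 30 days, and BOLA-DQB1 for age had an adjusted p of 0.0515 with it. Of 23 named genotype genes besides DLK1, 0 passed in every setting, all 23 being lost with least squares, and 379 of 506 values kept their direction and side of the threshold. Arrays read dim genes near background, so that changes below the filter were limited by signal.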

Other observations

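The values in this part were chosen after the data were seen.

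Of 7 probe sets that passed for both genotype and the change from 10 to 30 days, 3 had opposite signs. KLF10 stood at -1.17 for genotype and 0.89 for age, CIAPIN1 at 0.74 and -1.04, and a probe set with no symbol at -1.14 and 1.28. DNTTIP1 stood at 1.73 and 0.83, PAK1 at -0.90 and -1.18, MADCAM1 at -1.19 and -1.22 and SLC25A11 at -0.44 and -0.72. Further PAK1 probe sets gave -0.44 (adjusted p = 0.289) and -0.37 (adjusted p = 0.586) for genotype. A further KLF10 probe set gave 0.90 for age (adjusted p = 0.275). A brighter MADCAM1 probe set gave 0.14 and -0.10 and passed for neither. From 10 to 30 days DLK1 changed by 0.60 in callipyge and by -0.69 in normal lambs. The normal 30 day lambs lay far apart (SD 0.67), and the further DLK1 probe set changed by 0.10 in callipyge and by -0.17 in normal lambs. Across all tested probe sets, which are not independent replicates, the genotype difference correlated between ages at r = 0.206 (10 and 20 days), 0.211 (10 and 30 days) and 0.181 (20 and 30 days).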
